A study of Homo sapiens with 3 samples.

How the data were processed

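ChIP-seq of ERRγ was described for BT-474 cells under basal conditions, with 2 ERRγ libraries made with a custom antibody and 1 input library, 90 min after renewal of the medium. Per the submitters' processing notes, BWA 0.5.9, MACS 1.4.1 and HOMER 3.18 were used with the hg19 build. The notes give no role for each tool; the peak names and the annotation columns of the deposited table have the form that MACS and HOMER write. The threshold of the peak calling, read filters, the handling of duplicates and whether reads of both libraries were pooled before the calling are not given in the sources used here. The deposited table was 1 merged list, so a peak may rest on either library or on both, and reproducibility between the libraries could not be measured.

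Per the file headers, the deposited table gave for each peak its position, a score, the nearest TSS with the signed distance to it, an annotation of the position, the GC content, the CpG content and a mean conservation score. The deposited peak score was taken as a number without a known unit. MACS of this version reports a transformed p-value, but no header says that the column holds it, and 158 peaks tied at exactly 3100, so that the leading ranks are saturated. Scores rise with enrichment and with depth, and were not compared with any other list. The deposited GC content is a fraction between 0 and 1, although its header names a percentage. Peak coordinates are printed as the table gives them. Of 15223 peaks, 15153 (99.5%) had a gene identifier found in a RefSeq gene table of the GRCh38.p14 assembly, which was used for current symbols, biotypes and the order of neighbouring genes only. As the builds differ, none of its coordinates were used beside those of the peaks.

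The background was the 20037 protein-coding genes of the nuclear chromosomes. A gene was called bound when a peak named for it lay within 10 kb of the TSS. Because each peak names only its nearest TSS, the other gene of a paired promoter, or the host gene of a small RNA, is missed. A gene with a large intergenic neighbourhood is named more often when any distance counts. Each gene list was compared with all other background genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. Odds ratios of the contrasts have conditional exact 95% intervals and shares have exact Clopper-Pearson 95% intervals. A count of 0 was given the limit of 3 counts over the list size. Peak strength was the median over bound members of the strongest peak within 10 kb, placed among 10000 random lists of as many bound genes.

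The 24 lists with named genes were fixed before the data were examined, as were the tests, the distances and the alternatives, except where a comparison is said to have been added. They covered OXPHOS complex I, OXPHOS complexes II to V, the TCA cycle with pyruvate dehydrogenase, fatty acid oxidation, the mitochondrial ribosome, mitochondrial biogenesis and dynamics, glutathione metabolism, ROS detoxification, NRF2 targets, glutamine and glutamate metabolism, folate-dependent carbon transfer and serine metabolism, glycolysis, nuclear receptors, estrogen response genes, described ERR targets, the ERBB2 amplicon, luminal markers, basal and stromal markers, immune markers, the cytosolic ribosome, the proteasome, the spliceosome, sarcomere genes and neurotransmitter receptors. The olfactory receptors were taken by symbol as a further list. All listed symbols matched the gene table. Some genes belong to several lists, so the lists are not independent.

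Genes were named by a rule fixed beforehand. It took the 3 ERR genes, the 10 genes with the highest score within 10 kb, up to 4 members per list with the strongest peak within 10 kb, up to 4 members of each energy and redox list without such a peak in alphabetical order, and GCLC, GCLM, GSR, GPX4, SOD2, NQO1, ERBB2, TFF1 and PDK4. Ties in score were broken by the peak's name. Some genes that the rule selects are not reported here.

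The list test was tested on simulated data with the same 20037 genes. In 100 runs, lists planted with a 4-fold higher share of bound genes were called in 95% of cases, those with a 2-fold higher share in 44.5%, and lists without a planted difference in 0.375%. The 2-fold difference was planted in the mitochondrial ribosome and the nuclear receptors, with 77 and 48 members, so the power for smaller lists is lower. A list that is not called may therefore still differ by a factor of 2 or more. The upper 95% limit of the odds ratio was 7.03 for mitochondrial biogenesis and dynamics, 5.99 for ROS detoxification and 4.61 for NRF2 targets. Alternatives were a distance of 1 kb, 50 kb or any, the upper 50% and 10% of the peaks by score, leaving out chromosomes 17 and 20, a background of genes named in the table, members of several lists left out, and merging of peaks within 500 bp. In the background of genes named in the table every gene has a peak. That test therefore compares peaks within 10 kb with only farther ones. A search for the ERR response element was planned and was not run, as no genome sequence of the build was used here. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.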

Results

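The series profiled where estrogen-related receptor gamma (ERRγ, gene ESRRG), an orphan nuclear receptor known to regulate genes of mitochondrial energy metabolism, bound the genome of BT-474 cells, an established human breast cancer line of the luminal type with amplified ERBB2. Chromatin immunoprecipitation with sequencing (ChIP-seq) was run on vehicle-treated cells 90 min after their medium was renewed, with 2 ERRγ libraries and 1 input library, read as single 50 bp reads. The series title names the receptors as sensors of reactive oxygen species (ROS), so the comparisons below address which energy, redox and hormone-response genes had ERRγ peaks near them. The deposited table held 1 merged list of 15223 peaks on hg19 with no value per library. There was therefore no replicate spread, the read depth of each library is unknown here, and every interval below covers counting error only. Each peak carried the authors' score, which was used only to describe and rank peaks within this list.

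The gene of the related receptor ERRα, ESRRA, had a promoter peak among the strongest of the list, while the peak at the promoter of ESRRG itself was among the weakest of the list. The ESRRA peak covered chromosome 11, 64071145 to 64074443, was centred at -250 bp from the transcription start site (TSS; negative distances lie upstream) and scored 3100, and a further peak in intron 2 of 6 scored 55.3. ESRRG had 6 peaks, of which the promoter peak (chromosome 1, 217263081 to 217264034, -581 bp) scored 51.9 and the strongest, in intron 3 of 8 (216939678 to 216941040), scored 333. ESRRB had 1 peak, in intron 4 of 10, 75.4 kb from the TSS, with a score of 434. Over all peaks the score ran from 50 to 3227 with a median of 106.

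The highest-scoring peaks near genes lay at the promoters, in introns or in the flanks of genes of varied function. CCDC174 (C3orf19 in the table) had the highest score, 3227, at -104 bp from its TSS on chromosome 3 (14692460 to 14693838). SH2B1, an adaptor of receptor tyrosine kinase signalling, had a promoter peak of 3193, PLEKHF2 a peak of 3189 in its intron 1 of 1, and DGKZ, a diacylglycerol kinase, a peak of 3120 in intron 1 of 30. HIGD2A, an assembly factor of respiratory complexes whose promoter is shared with NOP16, scored 3100 at -52 bp. The cyclophilin gene PPIA scored 3100 at -369 bp. TEAD3, BMP5, HOXA13 and DRC8 (EFCAB2 in the table) also scored 3100, with peaks at 9208, -7507, 3467 and 923 bp from the TSS. As 158 peaks shared the score of exactly 3100 and only 17 exceeded it, the order among the genes with 3100 has no meaning. A tie below higher scores is not a plain ceiling, and the unit of the score is not known. Whether the leading 4 genes had stronger peaks than the tied ones is therefore unknown.

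Most ERRγ peaks lay far from promoters, and the share at promoters rose with the score. Of 15223 peaks, 7897 (51.9%, exact 95% interval 51.1 to 52.7) were annotated as intergenic and 6333 (41.6%, 40.8 to 42.4) as intronic. Within 1 kb of a TSS lay 917 peaks (6.02%, 5.65 to 6.41), and 7841 (51.5%) were more than 50 kb away. Of the 10% of peaks with the highest scores, 167 of 1522 were within 1 kb (10.97%, 9.45 to 12.7), against 59 of 1523 of the 10% with the lowest (3.87%, 2.96 to 4.97). Promoter peaks had a median GC fraction of 0.540, against 0.395 for peaks beyond 10 kb, and a median score of 163 against 101. The authors' own promoter annotation was narrower and took in 569 peaks (3.74%). The median peak width was 1219 bp, and all peaks together covered 22.6 Mb.

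**Figure D1:**
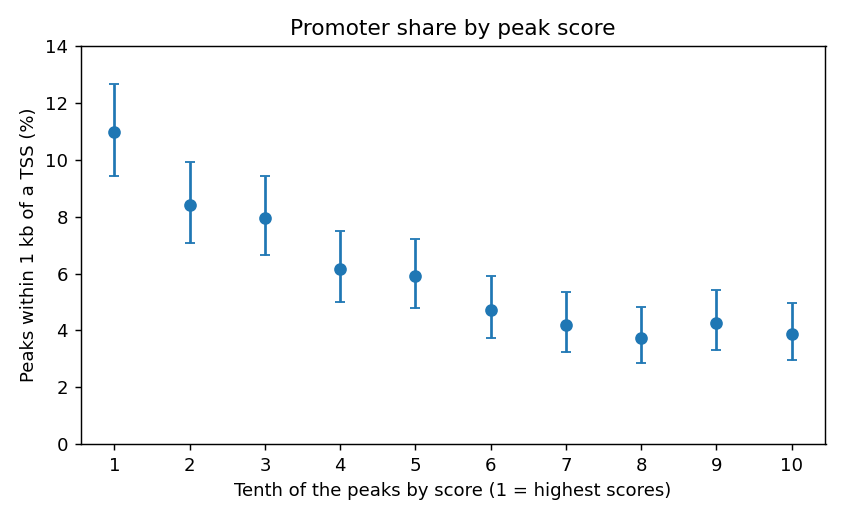
Share of peaks within 1 kb of a TSS (percent, points) with its exact 95% interval (bars) in each of 10 equal parts of the 15223 peaks ordered by the authors' score, 1 being the highest. The share was 10.97% in the part with the highest scores and 3.87% in that with the lowest.

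By the authors' nearest-gene annotation, 2301 of 20037 protein-coding genes (11.5%, exact 95% interval 11.05 to 11.93) had at least 1 peak within 10 kb of the TSS, and such genes are called bound below. The count depended on the distance, with 834 genes (4.16%) at 1 kb and 4520 (22.6%) at 50 kb, and on the score, with 1450 genes from the upper 50% of the peaks and 366 from the upper 10%. Of 25 gene lists, 12 had more bound members than the other protein-coding genes by Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over the 25 lists), 0 had fewer, and 13 were not called. These p-values compare genes within 1 peak list and not replicate experiments.

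**Figure D2:**
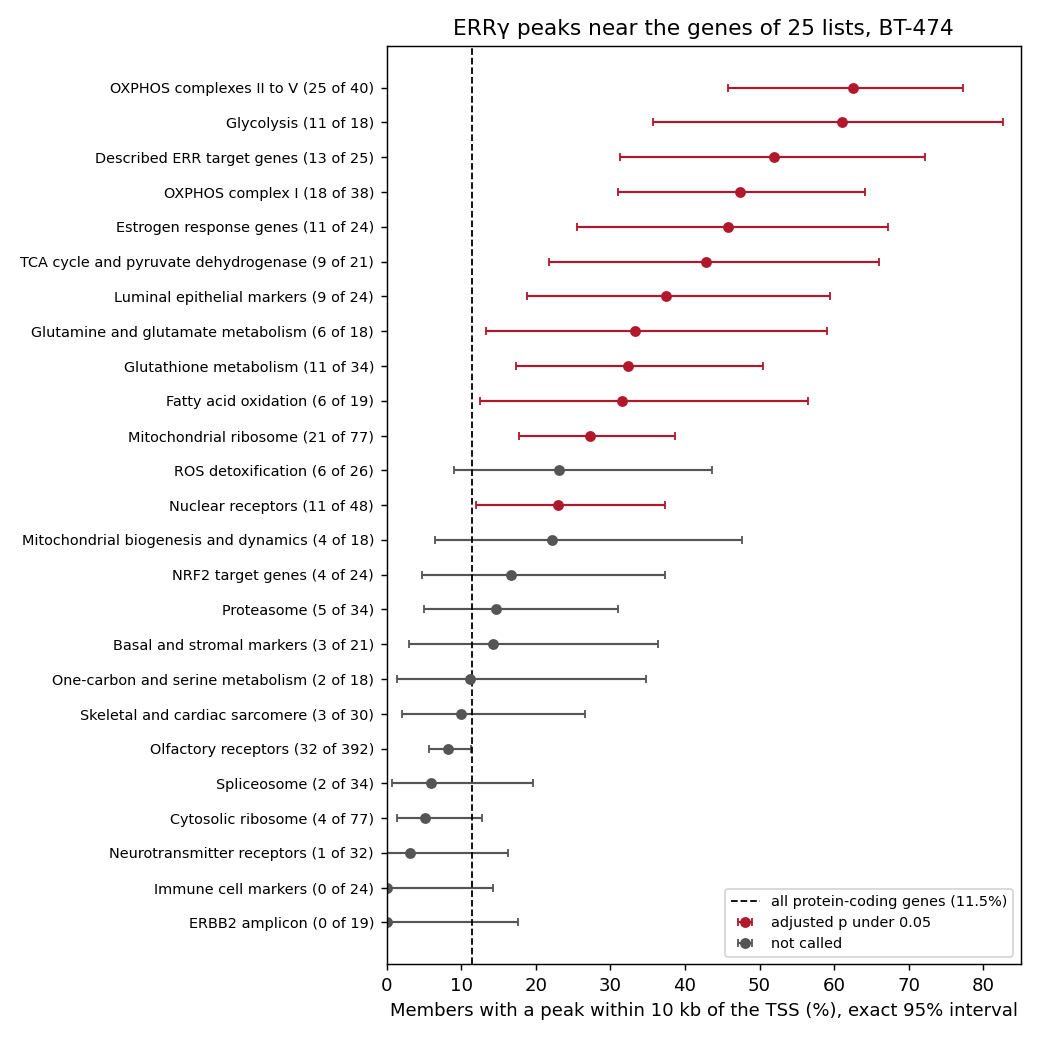
Share of the members of each of 25 gene lists with an ERRγ peak within 10 kb of the TSS (percent, points) and its exact 95% interval (bars), with the share of all 20037 protein-coding genes (11.5%) as a dashed line. Lists in red had an adjusted p under 0.05 in Fisher's exact test, led by OXPHOS complexes II to V at 62.5%, and the ERBB2 amplicon and immune cell markers had 0 bound members.

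Genes of the respiratory chain carried ERRγ peaks at their promoters more often than other genes. Of the 40 genes of oxidative phosphorylation (OXPHOS) complexes II to V, 25 were bound (62.5%, exact 95% interval 45.8 to 77.3; odds ratio 12.98, adjusted p = 5.02e-13), 24 of them within 1 kb. The peaks of the ATP synthase genes ATP5F1B (ATP5B in the table) and ATP5MC3 (ATP5G3) scored 3100, at 338 and 187 bp from the TSS, and those of ATP5F1A (ATP5A1) and the cytochrome c oxidase gene COX7A2 scored 1762 and 1498. The ATP5F1B peak, on chromosome 12 from 57038290 to 57040738, also covered the start of the small nucleolar RNA gene SNORD59A. The ATP synthase genes ATP5F1D, ATP5F1E and ATP5MC1 had no peak, and ATP5MC2 had 1 of score 51.2 at 17.3 kb. No peak at any distance was named for the 4 complex II genes, SDHA, SDHB, SDHC and SDHD, which are named after their values were seen. This naming misses genes at shared promoters. With the gene of the annotated promoter transcript also counted, a choice made after the data were seen, 26 of 40 complex II to V genes were bound. So were 10 of 21 TCA cycle genes, 19 of 38 complex I genes and 54 of 95 of these lists pooled. Only complex II genes are on both of the first lists, so a complex II gene was among those gained. Of 38 complex I genes 18 were bound (47.4%, 31.0 to 64.2; odds ratio 6.98, adjusted exact p = 4.89e-07), all within 1 kb. The strongest were NDUFB5, whose promoter is shared with MRPL47 (score 1963), NDUFS7 (998), NDUFA4 (777) and NDUFA6 (497), whereas NDUFA1, NDUFA10, NDUFA11 and NDUFA13 had no peak. NDUFA4 is now assigned to complex IV as COXFA4 and was on the fixed complex I list; counted with complex IV, a choice made after the data were seen, it left 17 of 37 complex I genes bound (odds ratio 6.59, adjusted exact p = 2.04e-06). The complex I call was lost when peaks at any distance counted (odds ratio 2.14, adjusted exact p = 0.0573) and with the upper 10% of the peaks (odds ratio 4.64, adjusted p = 0.133).

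The tricarboxylic acid (TCA) cycle and pyruvate dehydrogenase genes had 9 of 21 members bound (42.9%, exact 95% interval 21.8 to 66.0; odds ratio 5.80, adjusted p = 0.000985), all 9 within 1 kb. IDH3A, of the NAD-dependent isocitrate dehydrogenase, scored 1212 in intron 1 of 10, the citrate synthase gene CS 1000 at -2053 bp, and MDH2, with a promoter shared with STYXL1, 404. DLST, FH, IDH3G and PDHA1 had no peak. In fatty acid oxidation 6 of 19 genes were bound (31.6%, 12.6 to 56.6; odds ratio 3.56, adjusted exact p = 0.0374), led by CPT1A, the rate-controlling carnitine palmitoyltransferase of the liver type, with 1637 at -2260 bp. ECI2, ETFA and ACADM followed with 357, 237 and 196, and ACAA2, ACADL, ACADS and ACADVL had no peak. The TCA call was lost at 50 kb (odds ratio 2.58, adjusted exact p = 0.0734) and any distance (odds ratio 1.78, adjusted p = 0.319). The fatty acid oxidation call was lost at 1 kb (odds ratio 2.71, adjusted exact p = 0.358), at 50 kb (1.59, adjusted p = 0.539), at any distance (1.39, adjusted p = 0.577) and with the upper 10% of the peaks (2.99, adjusted p = 0.568).

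Mitochondrial ribosomal protein genes were bound above the background, with 21 of 77 members (27.3%, exact 95% interval 17.7 to 38.6; odds ratio 2.91, adjusted p = 0.000467). MRPL34 scored 3100, MRPL12 1203, MRPL48 1185 and MRPL15 828, all within 1 kb of the TSS, and DAP3, MRPL10 and MRPL11 had no peak, with MRPL13 having 1 of score 50.7 at 21.9 kb. With the upper 10% of the peaks 4 of 77 were bound, which kept the odds ratio at 2.97 and lost the call (adjusted exact p = 0.179), and at any distance the odds ratio fell to 1.44 (adjusted p = 0.228). Regulators of mitochondrial biogenesis and dynamics had 4 of 18 members bound (22.2%, 6.41 to 47.6; odds ratio 2.20, adjusted exact p = 0.212), which did not pass the test at 10 kb and passed it at 1 kb (odds ratio 6.61, adjusted p = 0.0159). The 4 were GABPA, a subunit of nuclear respiratory factor 2 (510), the mitochondrial DNA polymerase gene POLG (279), and the fusion genes OPA1 (164) and MFN2 (94.3). DNM1L, FIS1, MFN1 and NRF1 had no peak.

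Housekeeping genes were bound less often than the pooled energy and redox genes, though the difference did not pass the test for every list taken alone. The pooled genes of the cytosolic ribosome, proteasome and spliceosome, which most cells express highly, had 11 of 145 members bound (7.59%, exact 95% interval 3.85 to 13.2). Against them, the pooled OXPHOS and TCA cycle genes had 52 of 95 bound (54.7%, 44.2 to 65.0; odds ratio 14.7, 95% interval 6.76 to 33.8, adjusted p = 1.22e-15, Fisher's exact test over 3 contrasts), 51 of them within 1 kb. The OXPHOS, TCA cycle, fatty acid oxidation and mitochondrial ribosome lists together, without the list of biogenesis and dynamics, had 79 of 191 bound (41.4%; odds ratio 8.59, 4.26 to 18.7, adjusted exact p = 1.07e-12). The pooled redox lists had 20 of 77 bound (26.0%; odds ratio 4.27, 1.80 to 10.5, adjusted exact p = 0.000375). Taken alone against the housekeeping genes, in a comparison added after the data were seen, NRF2 targets (odds ratio 2.44, 95% interval 0.512 to 9.24, adjusted exact p = 0.343) and mitochondrial biogenesis and dynamics (3.48, 0.706 to 13.8, adjusted p = 0.103) were not called. Separately, the cytosolic ribosome had 4 of 77 bound (5.19%; odds ratio 0.421, adjusted exact p = 0.174), with RPL21 the strongest at 149, followed by RPL6 (130), RPS12 (107) and RPS14 (74.7). The proteasome had 5 of 34 (14.7%; odds ratio 1.33, adjusted exact p = 0.665), with PSMD12, PSMD5, PSMA3 and PSMD2 between 84.7 and 93.9, and the spliceosome 2 of 34 (5.88%; odds ratio 0.481, adjusted p = 0.505), SF3A3 with 81.4 and SF3B3, whose promoter is shared with COG4, with 53.0. The cytosolic ribosome genes were called as less often named when the distance was 50 kb (odds ratio 0.397, adjusted exact p = 0.0248).

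Several energy lists also had strong peaks at their bound genes, as did some lists outside energy metabolism. The median of each gene's strongest peak within 10 kb was 607 over the bound complex II to V genes, above 100% of 10000 random lists of as many bound genes, 369 over complex I (above 99.2%), 384 over the TCA cycle (above 96.0%) and 498 over glutathione metabolism (above 99.1%). It was 208 over the mitochondrial ribosome (above 83.6%), 216 over fatty acid oxidation (above 69.9%), 222 over mitochondrial biogenesis and dynamics (above 66.1%), 223 over NRF2 targets (above 64.9%) and 165 over ROS detoxification (above 52.3%). The proteasome and cytosolic ribosome medians were 88.7 and 118 (above 15.1% and 27.7%), and that of the olfactory receptors was 69.1 (above 0%). The 3 bound sarcomere genes, also a control, had a median of 397 (above 86.6%), a higher percentile than the mitochondrial ribosome and fatty acid oxidation. Among the remaining lists, the median was 517 over described ERR targets (above 99.6%), 421 over glycolysis (above 97.9%) and 306 over nuclear receptors (above 93.6%). It was 299 over glutamine and glutamate metabolism (above 85.1%) and 228 over estrogen response genes (above 82.1%). Luminal markers had 146 (above 46.1%), and basal and stromal markers 90.2 (above 20.6%). These percentiles describe 1 list and carry no p-value.

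Among the redox genes, glutathione metabolism was bound above the background, whereas ROS detoxification and the targets of the oxidative stress regulator NRF2 were not called, and the difference between these lists was not tested. Glutathione metabolism had 11 of 34 members bound (32.4%, exact 95% interval 17.4 to 50.5; odds ratio 3.70, adjusted p = 0.00286). IDH2, a mitochondrial source of NADPH, scored 3100 in intron 1 of 10 at 6842 bp, the glutathione S-transferase gene GSTP1 2020 at -1475 bp, and GGCT 589 at -9607 bp. The glutathione reductase gene GSR had 2 peaks in intron 1 of 10, the stronger (chromosome 8, 30580075 to 30581361) scoring 541 and the other, at 908 bp, 296. Of the glutamate-cysteine ligase genes, which make the rate-limiting enzyme of glutathione synthesis, GCLM had no peak and GCLC had 4, all beyond 10 kb, the strongest scoring 1263 at 79.8 kb (chromosome 6, 53328924 to 53331283, intergenic). CHAC1 and the lipid peroxidase gene GPX4 had no peak. The glutathione call was lost with the upper 10% of the peaks (odds ratio 3.37, adjusted exact p = 0.319), at any distance (2.11, adjusted p = 0.0767) and against only genes named in the table (3.49, adjusted p = 0.0526).

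ROS detoxification had 6 of 26 members bound (23.1%, exact 95% interval 8.97 to 43.6; odds ratio 2.32, adjusted p = 0.175), led by the thioredoxin reductase gene TXNRD1 with 227 at -816 bp, SESN1 (184), TXN2 (182) and the catalase gene CAT (148 at -4905 bp). GLRX, GLRX2, GLRX3, GLRX5 and the mitochondrial superoxide dismutase gene SOD2 had no peak. Against the housekeeping genes alone, a comparison added after the data were seen, ROS detoxification passed the threshold by p (odds ratio 3.65, adjusted exact p = 0.0447), while the 95% interval of the odds ratio, 0.985 to 12.2, included 1. NRF2 targets had 4 of 24 bound (16.7%, 4.74 to 37.4; odds ratio 1.54, adjusted exact p = 0.435), all 4 within 1 kb, and were called at that distance (odds ratio 4.62, adjusted p = 0.0370). TKT, of the pentose phosphate pathway, scored 3100 at -296 bp, ABCC2 219 at -48 bp, and NQO1, a classical NRF2 target, 72.7 in intron 1 of 4 at 246 bp. ABCC3, AKR1B10, AKR1C1 and EPHX1 had no peak.

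Glycolysis genes were also bound above the background, with 11 of 18 genes (61.1%, exact 95% interval 35.7 to 82.7; odds ratio 12.2, adjusted p = 4.98e-06), 10 of them within 1 kb. ALDOA scored 1270 in intron 1 of 8, HK1, which had 4 peaks within 10 kb, 927, the pyruvate kinase gene PKM 863 at 41 bp and ENO1 804 at -209 bp. Glutamine and glutamate metabolism had 6 of 18 bound (33.3%, 13.3 to 59.0; odds ratio 3.86, adjusted exact p = 0.0311). The aspartate aminotransferase genes GOT1 and GOT2 scored 2391 and 386, GPT2 353 and the glutamine transporter gene SLC38A1 244. This call was lost at 1 kb, where 3 of 18 were bound and the odds ratio was 4.62 (adjusted exact p = 0.0766), at 50 kb (odds ratio 2.75, adjusted p = 0.0759), at any distance (2.38, adjusted p = 0.136), with the upper 10% of the peaks (3.17, adjusted p = 0.568) and against only genes named in the table (3.17, adjusted p = 0.204). Folate-dependent carbon transfer and serine metabolism had 2 of 18 bound (11.1%, 1.38 to 34.7; odds ratio 0.963, adjusted exact p = 1), PHGDH with 860 at 6821 bp and MTHFD2 with 98.9 at 7428 bp.

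Estrogen response genes and luminal markers were bound as well, mostly away from the promoter. Estrogen response genes had 11 of 24 members bound (45.8%, exact 95% interval 25.6 to 67.2; odds ratio 6.55, adjusted p = 0.000134), but only 2 within 1 kb, and 21 of 24 were named by a peak at any distance. RARA scored 880 in intron 1 of 6 at 4199 bp, TFF1, a classical estrogen-induced gene, 517 at its promoter (chromosome 21, 43786218 to 43787517, -223 bp), CA12 382 at -5964 bp and GREB1 324 at -1157 bp. Luminal epithelial markers had 9 of 24 bound (37.5%, 18.8 to 59.4; odds ratio 4.64, adjusted exact p = 0.00278), 1 within 1 kb. KRT8 scored 3100 at 9656 bp, ERBB3 1321 at -921 bp, ELF3 322 at its 3' UTR and KRT18 314 at -2562 bp. Neither list was called at 1 kb (odds ratios 2.10 and 1.001, adjusted exact p = 0.471 and 1), with the upper 10% of the peaks (2.34 and 4.91, adjusted p = 0.596 and 0.196) or against only genes named in the table (1.74 and 1.42, adjusted p = 0.490 and 0.755). Both were called with the upper 50% of the peaks (7.73 and 6.44, adjusted exact p = 0.000107 and 0.000593). They were also called at 50 kb (8.36 and 10.3, adjusted exact p = 5.4e-06 and 8.93e-07) and at any distance (16.7 and 9.05, adjusted p = 7.39e-08 and 6.17e-06).

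Of the genes described in the literature as ERR targets, a list that shares members with the energy lists, 13 of 25 were bound (52.0%, exact 95% interval 31.3 to 72.2; odds ratio 8.39, adjusted p = 4.98e-06), among them ATP5F1B, ESRRA and IDH3A. The call was lost when peaks at any distance counted (odds ratio 2.58, adjusted exact p = 0.0580). PDK4, an inhibitor of pyruvate dehydrogenase, had 6 peaks, the strongest of which scored 1296 at 48.5 kb (chromosome 7, 95176609 to 95178201, intergenic), with 79.6 for the only one within 10 kb, in exon 10 of 11. Nuclear receptor genes had 11 of 48 bound (22.9%, 12.03 to 37.3; odds ratio 2.30, adjusted exact p = 0.0437), with RARA (880), NR2F6 (860) and NR0B2, the small heterodimer partner (453), next to ESRRA. That call was near the threshold and was lost without chromosomes 17 and 20 (odds ratio 1.97, adjusted exact p = 0.163), at 50 kb (1.89, adjusted p = 0.0736), with the upper 10% of the peaks (3.604, adjusted p = 0.179) and against only genes named in the table (1.02, adjusted p = 1). It was kept at 1 kb (3.31, adjusted exact p = 0.0353), with the upper 50% of the peaks (2.57, adjusted p = 0.0400) and at any distance (28 of 48, 3.34, adjusted p = 0.000215).

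Markers of other cell types and genes silent in breast epithelium were not bound above the background. Basal and stromal markers had 3 of 21 bound (14.3%; odds ratio 1.29, adjusted exact p = 0.790), PECAM1, COL1A2 and KDR, with scores from 68.9 to 129. Immune cell markers had 0 of 24, which allows a share of up to 12.5% (adjusted p = 0.174, Fisher's exact test). Sarcomere genes had 3 of 30 bound (10%; odds ratio 0.856, adjusted exact p = 1), of which MYBPC3 scored 2628 at -2249 bp next to SPI1, TNNT2 397 and TTN 52.4. Neurotransmitter receptors had 1 of 32 (3.13%; odds ratio 0.248, adjusted exact p = 0.225). Olfactory receptors had 32 of 392 (8.16%, exact 95% interval 5.65 to 11.3; odds ratio 0.681, adjusted p = 0.0716), with OR6B1, OR1C1, OR4K5 and OR10V1 between 221 and 274. The peaks at OR1C1 and OR4K5 were 8673 and 6375 bp wide. With the upper 50% of the peaks the olfactory receptors were called as less often bound (odds ratio 0.163, adjusted exact p = 5.05e-07). They were also called as less often named at any distance (odds ratio 0.374, adjusted exact p = 3.23e-12). Among only genes named in the table, their peaks more often lay within 10 kb (32 of 54, odds ratio 2.32, adjusted exact p = 0.0102). Some of these genes are neighbours, as in a run of 50 genes without a named peak from OR4C12 to OR9G4. The tests treat them as independent, so these p-values cannot be relied on.

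No gene of the ERBB2 amplicon was bound. All 19 listed genes, ERBB2 included, lacked a peak at any distance. Taken as separate genes, 0 of 19 allows a share of up to 15.8% (adjusted p = 0.218, Fisher's exact test, with 0.0295 at 50 kb and 0.0064 at any distance). However, all 19 are neighbours within the same stretch without a peak, described next. The limit and the p-values treat them as independent genes, which they are not, so neither can be relied on here. On chromosome 17 no peak lay between 35277989 and 38256897, a distance of 2.98 Mb from the peak named for LHX1 to that named for NR1D1, against a median of 73.9 kb between neighbouring peaks in the list; 35 other gaps on the autosomes, where centromeres are not marked here, were as long. Peaks were densest on chromosomes 14, 8 and 7, with 9.26, 8.69 and 7.28 peaks per Mb between the outermost peaks, and sparsest on the X chromosome with 2.41. Chromosome Y was left out of these densities. Chromosome 17 had 5.38 and chromosome 20 had 4.44 per Mb. The median score of the peaks was 82.1 on chromosome 8 and 93.8 on chromosome 14, against 120 on chromosome 17. Of the 10% of peaks with the highest scores, chromosome 14 nevertheless had 0.797 per Mb, the highest density of all, against 0.756 on chromosome 17 and 0.604 on chromosome 8.

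**Figure D3:**
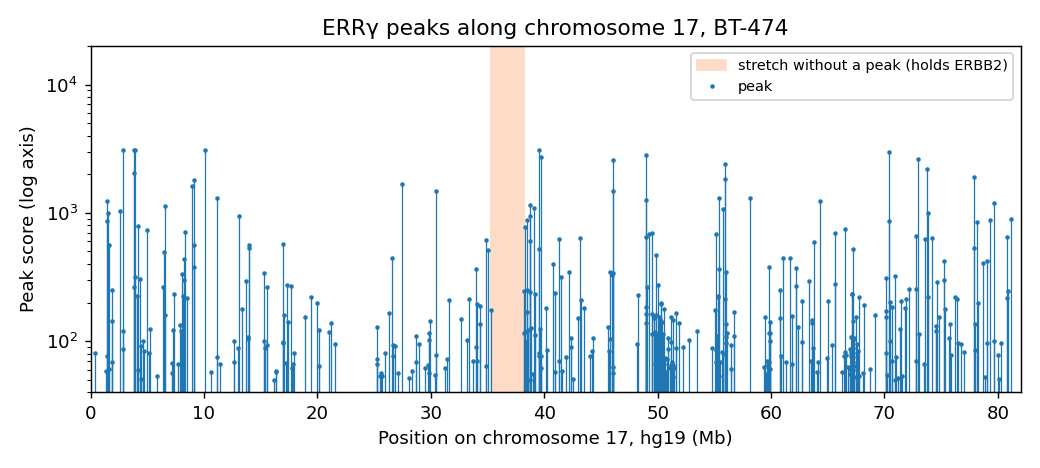
Peaks along chromosome 17 (hg19, position in Mb on the horizontal axis) with the authors' score on a logarithmic vertical axis, each point and line being 1 peak. The shaded stretch of 2.98 Mb, which holds ERBB2, has no peak.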

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

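The detailed annotation column, which the comparisons above do not use, places 5275 of the 15223 peaks (34.7%, exact 95% interval 33.9 to 35.4) in a repeat. It was examined because signal in repeats stands outside the gene comparisons. The share of the genome in each repeat class and the copy number of each element were not used here. Whether the counts below are high or low for their class is therefore unknown. LINE elements held 2130 peaks (13.99%) with a median score of 82.6, SINE elements 1510 (9.92%) with 115 and LTR elements 1159 (7.61%) with 103, against 113 for the 9948 peaks in no repeat. The share in LINE elements was 7.42% among the 10% of peaks with the highest scores and 19.3% among the 10% with the lowest. Among LTR elements, LTR8 held 34 peaks, MLT1J 32, MER11B 28 and HERV17-int 21, the last with a median score of 205. Satellite repeats held 20 peaks (0.131%) with a median score of 74.4 and a highest score of 3100. The values of the input library at these repeats were not used here, so no explanation was tested.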

How the results depend on the processing

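No paired analysis was possible because the merged list has no value per library, and leaving out a replicate could not be run for the same reason. The motif alternatives and the other strength column were not run. Choices added after seeing the data were leaving out the 5% of 1 Mb bins with the most peaks, a background without LOC symbols or of housekeeping genes only, counting genes named by the annotated promoter transcript, and counting NDUFA4 with complex IV. The 3 contrasts with housekeeping genes kept their direction and call under every alternative that gave an odds ratio, those of the OXPHOS and TCA genes running from 5.78 (any distance) to 46.3 (upper 50% of the peaks). With the upper 10% of the peaks 0 of 145 housekeeping genes were bound, so no finite odds ratio exists; 19 of 95 OXPHOS and TCA genes were bound (adjusted exact p = 2.04e-08) and 3 of 77 redox genes (adjusted p = 0.0407), for which the lower limit of the odds ratio, 0.788, was under 1. The peak count fell at most to 14889, with peaks within 500 bp merged, and the strength percentile of the OXPHOS and TCA genes to 99.99%.

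The number of bound genes moved to 834 at 1 kb, 4520 at 50 kb, 5938 at any distance, 1450 with the upper 50% and 366 with the upper 10% of the peaks. The promoter share moved from 6.02% to 3.74% by the authors' annotation, 7.88% and 10.97% in the upper 50% and 10%, and 6.87% without the densest bins. The lists called fell from 12 to 8 at 50 kb, 5 at any distance and 4 with the upper 10%, all of them among the 12, and to 8 against only genes named in the table, where 5 of the 12 were lost and the olfactory receptors gained. The background of named genes compares near peaks with farther ones, and not bound genes with genes that lack a peak. OXPHOS complexes II to V and glycolysis were called under every alternative run. At 1 kb 10 lists were called, 8 of them among the 12. Leaving aside the background of housekeeping genes only, there were 270 list odds ratios under alternatives. Of these, 205 kept direction and side of the threshold, 29 lost and 13 gained a call in the same direction, and 23 changed direction, 0 of them in a list called in the main analysis. Of those 23, 1 passed the threshold, that of the olfactory receptors against only genes named in the table. The cause of these changes was not tested. The odds ratios that changed direction were as follows. Against only genes named in the table they were 3.16 for folate and serine metabolism, 1.19 for sarcomere genes and 2.32 for olfactory receptors. At 1 kb they were 0 for basal markers, 0.697 for the proteasome and 1.44 for the spliceosome. At 50 kb they were 0.981 for mitochondrial biogenesis, 0.890 for the proteasome and 1.04 for sarcomere genes. At any distance they were 0.913 for mitochondrial biogenesis, 0.730 for the proteasome and 1.63 for neurotransmitter receptors. With the upper 50% they were 0.641 for basal markers and 0 for the proteasome. With the upper 10% they were 0 for mitochondrial biogenesis, ROS detoxification, basal markers and the proteasome, 3.17 for folate and serine metabolism and 1.86 for sarcomere genes. Without chromosomes 17 and 20 they were 1.02 for folate and serine metabolism and 1.15 for sarcomere genes, and without the densest bins 1.05 for folate and serine metabolism. Against housekeeping genes only, which the 270 leave out, further odds ratios changed direction without a call. They were 1.52 for folate and serine metabolism, 1.35 for sarcomere genes and 1.08 for olfactory receptors. There 13 lists were called, the 12 of the main analysis and ROS detoxification.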

Other observations

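Gene families grouped by symbol root, chosen after the data were seen, add mitochondrial protein import to the groups above. Of 385 families with at least 8 members, 5 had more bound members than other genes (Fisher's exact test, Benjamini-Hochberg adjusted over the families). They were the cytochrome c oxidase family COX (13 of 26, adjusted exact p = 0.000805), the small mitochondrial ribosomal subunit MRPS (12 of 28, adjusted p = 0.00714), the complex I family NDUFS (6 of 8, adjusted p = 0.00809), the inner membrane translocases TIMM (8 of 15, odds ratio 8.51, adjusted p = 0.0112) and the mixed ATP root (22 of 86, adjusted p = 0.0447). TIMM genes were on none of the fixed lists. TIMM10 scored 1697 at 335 bp, TIMM8B 1632 at 198 bp, TIMM9 522 at 77 bp and TIMM21 367 at -16 bp. The ATP root pooled ATP synthase genes with ion pumps such as ATP1B1, a subunit of the sodium pump with a peak of 3100 at -37 bp.

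Where the bound genes had their peaks differed between groups, in a comparison also chosen after the data were seen. Of the bound OXPHOS and TCA genes 51 of 52 had a peak within 1 kb, against 3 of 20 bound estrogen response and luminal genes (p = 1.44e-12, Fisher's exact test). Several estrogen response and luminal genes without a peak within 10 kb were named by strong distal ones, among them XBP1 with 2635 at -18585 bp, NRIP1 with 2166 at -145279 bp, CCND1 with 1271 at -125567 bp and AGR3 with 3099 at -54812 bp. The genes named by most peaks at any distance, a count that favours genes with large intergenic surroundings, were the GATA-type regulator TRPS1, with 55 peaks, CDH18 with 45, CDH9 with 41 and FBXO33 with 35. TBX3 had 24, as did AUTS2, KCNV1 and NOVA1. FOXA1, a pioneer factor of luminal cells, had 20, as did CNTN5, SNX16 and TRIQK. The peaks of TRPS1, CDH18, CDH9, FBXO33, TBX3 and FOXA1 were mostly weak and distant. Their median scores ran from 64.0 (CDH9) to 97.5 (TBX3), against 106 over all peaks. Their median distances ran from 105 kb (FOXA1) to 750 kb (FBXO33).

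Technical explanations were weighed for 3 patterns; the tests of paired promoters and of weak peaks in the pooled genes were written down before their results were seen, and the other tests only afterwards. Among the latter, the least number of bins per chromosome was raised after a first, more extreme value was seen, and the tests of chance for the chromosome 17 stretch replace earlier ones that only ranked it among observed stretches. The first pattern is the frequent binding of OXPHOS and TCA genes. Active promoters in general would give housekeeping genes as many peaks, but the odds ratio against them was 14.7. Naming of housekeeping promoters for a paired or small RNA gene could hide their peaks. With the annotated promoter transcript counted the odds ratio was 14.6, as 12 of 145 housekeeping genes were then bound. This adds only the gene of that transcript, and all bound genes rose only from 2301 to 2371. A gene that neither annotation names stays missed, so the test cannot exclude this explanation. Weak peaks near the threshold would vanish in the upper 10% of the peaks, where 19 of 95 of these genes and 0 of 145 housekeeping genes were bound and the lower limit of the odds ratio was 8.52. By list, in a test added after the data were seen, complexes II to V (13 of 40, lower limit 14.9) and the TCA cycle (3 of 21, lower limit 3.03) kept an excess among these strongest peaks. Their excess therefore does not rest on weak peaks alone. With all peaks 25 and 9 of these genes were bound, and the test does not cover those that were lost. For complex I this test leaves weak peaks open, as 3 of 38 remained, with a lower limit of 1.62 against housekeeping genes and no call against all other genes (odds ratio 4.64, adjusted exact p = 0.133). With the upper 50% of the peaks, which scored at least 106 against a lowest score of 50, 15 of 38 complex I genes remained bound (odds ratio 8.44, adjusted exact p = 2.87e-07). The excess of complex I was thus present without the lower 50% of the peaks. The 15 genes were kept because of their scores, so those scores are no test of weak peaks. Selective binding at these promoters remains a hypothesis, and other sources such as the antibody's specificity among ERR proteins were not tested, as the series has no group that would test them.

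The second pattern is the stretch of chromosome 17 that holds ERBB2 and no peak. It spans 58 consecutive protein-coding genes from AATF to THRA without a named peak. Even chance placement along the chromosome is excluded, as the longest gap in 10000 random placements of its peaks was 2.73 Mb. Uneven spacing as elsewhere in the list is not: 7.27% of the autosomal span lies in other gaps as long, which may include centromeres, and 0.677% of autosomal genes in other runs of as many genes, of 70 on chromosome 5 and 59 on chromosome 9. Peaks may be called less often in amplified segments, where the input is high as well. Of 14 genes from the 17q23 and 20q13 segments, described as amplified in this line, 3 were named by a peak (21.4%), against 29.6% of other genes (odds ratio 0.647, 95% interval 0.116 to 2.45, p = 0.770 by Fisher's exact test), which is too few genes to decide. Uneven spacing, lack of binding and lost calls therefore cannot be told apart without the read depth of the input.

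The third pattern is a crowding of AT-rich peaks with a lower median score. The 129 bins of 1 Mb with the most peaks held 2670 peaks, with a median score of 85.8, a median GC of 36.3% and a median distance of 94.6 kb to a TSS, against 113, 41.4% and 47.2 kb elsewhere, and 30 of them lie on chromosome 8 and 17 each on chromosomes 5 and 14. Of the peaks there 7.15% were among the 10% with the highest scores, against 10.6% elsewhere; per bin these were 1.48 against 0.548, an excess that the choice of bins by their number of peaks favours. If AT-rich sequence alone were the cause, bins with peaks as AT-rich would hold similar counts, but their median ran from 2 peaks on chromosome 4 to 19 on chromosome 14, a ratio of 9.5 over the 10 chromosomes with at least 20 such bins. This GC is that of the peaks and only bins with a peak have one, so the composition of the regions is unknown here and the explanation stays open. Gained copies of chromosome segments may contribute: 52.7% of the densest bins adjoin another, against 8.69% for random bins, but regional binding would cluster them too, and they cannot be told apart without the input.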
